A study of Mus musculus with 2 samples.

How the data were processed

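Messenger RNA levels were measured by RNA sequencing in MC3T3-E1 cells, a clonal mouse pre-osteoblast line derived from newborn calvaria, after culture with formaldehyde at 100 µM or 300 µM. There was 1 library per dose. The labels give neither the length of exposure nor a replicate, and untreated cells were not analysed here. No p-value was therefore computed, and each difference is one between 2 libraries.

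The authors deposited 1 gene-level table per library, in FPKM (fragments per kilobase of transcript, scaled to the library's number of mapped fragments) rounded to 2 decimals, per the file headers. Bowtie2 and RSEM are named in the submitters' processing notes, without versions. The genome build and annotation are not given in the sources used here, so no coordinates are printed. FPKM is relative to each library's total, so a few abundant transcripts that take a larger share lower all other values. An FPKM of RSEM also depends on how reads were divided among isoforms and near-identical copies.

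Both tables list the same 17215 genes in the same order. Symbols were looked up by NCBI gene number: 17179 were found in RefSeq genes of mouse assembly GRCm38, 7 more in GENCODE release M21, and 29 rows stayed unnamed. Transcript length, GC content and 3' UTR came from GENCODE release M21, from 1 representative transcript per gene, a coding one where available. Gene span, from the same release, ran from the first start to the last end of all the gene's transcripts on that chromosome. These properties were available for 10093 of the 10123 genes compared.

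Depth was read from the low values. Among genes with 1 annotated transcript, FPKM times transcript length fell on steps, the value of 1 read. A step of 54 bases at 100 µM placed 61.3% of 181 low values within 0.12 reads of a whole number, against at most 37.8% in 20 shuffles of the lengths. A step of 51.5 bases at 300 µM placed 66.0% of 147 values there, against at most 34.6%. These steps correspond to about 18500000 and 19400000 mapped fragments, and up to 21300000 in both if the effective length is shorter than the transcript. At 100 µM, a transcript of 1 kb at 5 FPKM then rests on about 93 reads, with an exact 95% Poisson interval of 75.1 to 113.9. Such intervals cover counting error only, and reads without molecular identifiers are not independent molecules.

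The comparison was log2((FPKM at 300 µM + 1)/(FPKM at 100 µM + 1)), for genes with a mean of at least 1 FPKM over the 2 libraries. The pseudocount of 1 understates the change of low genes. Genes at or beyond 2-fold on this scale were counted as higher or lower. In addition, 43 gene lists (1281 entries) were fixed from textbook knowledge before the data were examined, markers of other cell types among them. In all, 1193 entries matched a listed gene by symbol and 52 by an older symbol. Each list's median was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart in the bottom or the top 2.5% of these, as a description of these 2 libraries, since genes are not replicates. Lists with fewer than 3 compared genes were given no percentile.

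Genes are named by a rule fixed in advance. It takes the 12 with the largest ratio in each direction among genes with a mean of at least 5 FPKM (predicted genes left out). It adds up to 2 members per list and direction, and 20 fixed genes whatever their values. Some genes taken by this rule are not reported here. For each named gene, the share of the 50-base words of its transcript that occur in another gene's transcripts was computed from GENCODE release M21.

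The same steps were tested on simulated data, a pair of libraries drawn from the values at 100 µM with Poisson counts at the estimated depths. In this run of 10181 genes, all 50 genes changed 3-fold upward and all 50 changed 3-fold downward were recovered. The 50 and 50 changed 4-fold were recovered too. The changed genes did not include those of the lowest levels compared, where the pseudocount brings a 3-fold fall within 2-fold. Recovery of such low genes was therefore not tested, and they can be missed. Of 9981 unchanged genes, 0 passed the 2-fold size. Of 200 lists of unchanged genes, 4 stood apart. The simulation holds no variation between cultures.

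Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 FPKM, thresholds of 1.5-fold and 3-fold, centring on the median gene, and an unweighted TMM factor (trimming 30% of ratios and 5% of levels at each end). For the lists, unmatched random lists and the mean in place of the median were also tried. Removal of the trend with transcript length and GC content from the ratios, and random lists matched on transcript length as well as level (5 bins each), were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.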

Results

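The series compared mouse MC3T3-E1 pre-osteoblasts cultured with formaldehyde, a reactive aldehyde that crosslinks DNA and protein, at 100 µM and at 300 µM. Its title concerns the inhibition of osteoblast proliferation, so the question addressed here is how the transcriptomes at the lower and higher dose differ. Each dose is represented by 1 library, so no difference could be set against a spread between replicates. The libraries held an estimated 18500000 fragments at 100 µM and 19400000 at 300 µM. Of 17215 listed genes, 10206 reached 1 FPKM at 100 µM and 9332 at 300 µM, while 2961 and 3391 were listed at 0.

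The transcriptome at 300 µM was concentrated in fewer transcripts. The 100 most abundant genes held 37.7% of summed FPKM at 100 µM and 49.4% at 300 µM. Cytosolic ribosomal protein genes alone held 26.4% and 37.0%. The most abundant gene in both was Rpl41, a ribosomal protein gene, at 7190 FPKM and 13333 FPKM. Among the 10123 genes with a mean of at least 1 FPKM, 616 were at least 2-fold higher and 3020 at least 2-fold lower at 300 µM, so 83.1% of these genes were lower. The median gene had a log2 ratio of -0.30. After centring on that median, 1472 genes were higher and 2261 lower, and the share lower was 60.6%. Summed FPKM was 532944 at 100 µM and 691521 at 300 µM. On a scale of equal sums, which was not run, the ratios would therefore be lower, whereas centring and the TMM factor raise them. Small positive ratios thus depend on the scale chosen. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.86 and Spearman's rho was 0.81.

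The genes with the largest ratios at 300 µM were a mixed group. The heat shock gene Hspa1b stood at 10.4 FPKM at 100 µM and 163 FPKM at 300 µM, a log2 ratio of 3.84, and Hspa1a, with which it shares 62.3% of its 50-base words, at 0.19 and 7.30 FPKM. Pbld1 stood at 0.15 and 125 FPKM, and Cyp2e1, a cytochrome P450 gene, at 0.76 and 50.4 FPKM. Where in these genes the reads lie was not examined, because no reads were used here. Log2 ratios of Stxbp2, the chemokine receptor gene Cxcr2 and Cd300a were 3.82, 3.68 and 3.56. Sfxn4, Slc7a14 and the DNA repair nuclease gene Dclre1c (Artemis) had 2.90, 2.88 and 2.80. Tmem254b, at 0.15 and 24.8 FPKM, is uncertain, because 100.0% of its words occur in the copy Tmem254a, and a further copy, Tmem254c, stood at 11.3 and 0.85 FPKM. Churc1, at 34.9 and 337 FPKM, shares 54.4% of its words with other genes, Fntb foremost.

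The genes with the largest ratios in the other direction stood at 20.1 to 114 FPKM at 100 µM and at 0.32 to 5.31 FPKM at 300 µM. Sema7a, a semaphorin gene, stood at 33.4 FPKM at 100 µM and 0.49 FPKM at 300 µM (log2 ratio -4.53). Socs5, a suppressor of cytokine signalling, had a log2 ratio of -4.44, and the p53 targets Ddit4l and Trp53inp1 had -4.41 and -4.21. Gprc5a stood at 114 and 5.31 FPKM, the hyaluronan synthase gene Has2 at 24.4 and 0.44 FPKM, and Ereg, which encodes the growth factor epiregulin, at 63.7 and 2.78 FPKM. Odaph, Plec (plectin), Abl2 (a tyrosine kinase) and Slc19a2 (a thiamine transporter) had log2 ratios of -4.10, -4.09, -4.00 and -3.85. Akap2 had -4.06, but 94.6% of its words occur in the overlapping gene Pakap.

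Genes that p53 activates were lower at 300 µM than at 100 µM. Of 38 compared, 24 were at least 2-fold lower and 3 at least 2-fold higher (20 and 4 after centring on the median gene). The cyclin-dependent kinase inhibitor gene Cdkn1a (p21) stood at 604 FPKM at 100 µM and 117 FPKM at 300 µM. Mdm2, the p53 ubiquitin ligase gene, stood at 105 and 14.9 FPKM. Plk3 and Gadd45a went the other way, with log2 ratios of 2.28 and 1.60. Trp53 itself, at 113 and 138 FPKM, had a log2 ratio of 0.28. The list's median log2 ratio was -1.32, and 0 of 10000 random lists matched on level had a median as low.

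The lists of DNA replication genes and replication-dependent histones stood apart as higher at 300 µM. Of 48 genes of the G1/S transition and DNA replication, 15 were at least 2-fold higher and 4 lower (22 and 3 after centring), with a median of 0.67 that 0 of 10000 random lists reached. The primase gene Prim2 stood at 6.68 and 29.1 FPKM and the polymerase delta gene Pold1 at 16.9 and 48.2 FPKM. Ccne2 (cyclin E2) and the flap endonuclease gene Fen1 had ratios of -2.27 and -1.87. Of 14 histone genes, 7 were at least 2-fold higher and 0 lower, and 10 and 0 after centring (median 1.02, reached by 0 random lists), among them H4c9 and H3c1, whose sequences are shared with other histone genes in part. These 14 of 40 listed histone genes had low levels, with medians of 1.2 FPKM at 100 µM and 2.7 FPKM at 300 µM. Without the filter the median over 40 genes was 0.48, at percentile 100. The histone list was fixed in advance as a marker of RNA quality, so a link to replication was not tested. In the mitotic list 3 of 55 genes were higher and 6 lower (7 and 4 after centring), with a median of 0.07 at percentile 93.9. With the mean over members (-0.04) that list also stood apart as higher than random lists, at percentile 98.99. Within it Spc24 and Ube2c had log2 ratios of 1.28 and 1.13, while the proliferation marker Mki67 stood at 26.9 FPKM at 100 µM and 5.12 FPKM at 300 µM and Espl1 (separase) had -1.71. Ccnb1 (cyclin B1) had -0.09, a sign that flips after centring, and its transcript shares 42.1% of its words with a pseudogene and other copies. Among 12 cyclin-dependent kinase inhibitors and D cyclin partners, Cdkn1a, Ccnd2 and Ccnd1 were lower by at least 2-fold (-2.36, -2.03 and -1.43), and Cdk4 had 0.53 (list median -0.44, percentile 14.0, and 2.18 at a mean of at least 10 FPKM).

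**Figure D1:**
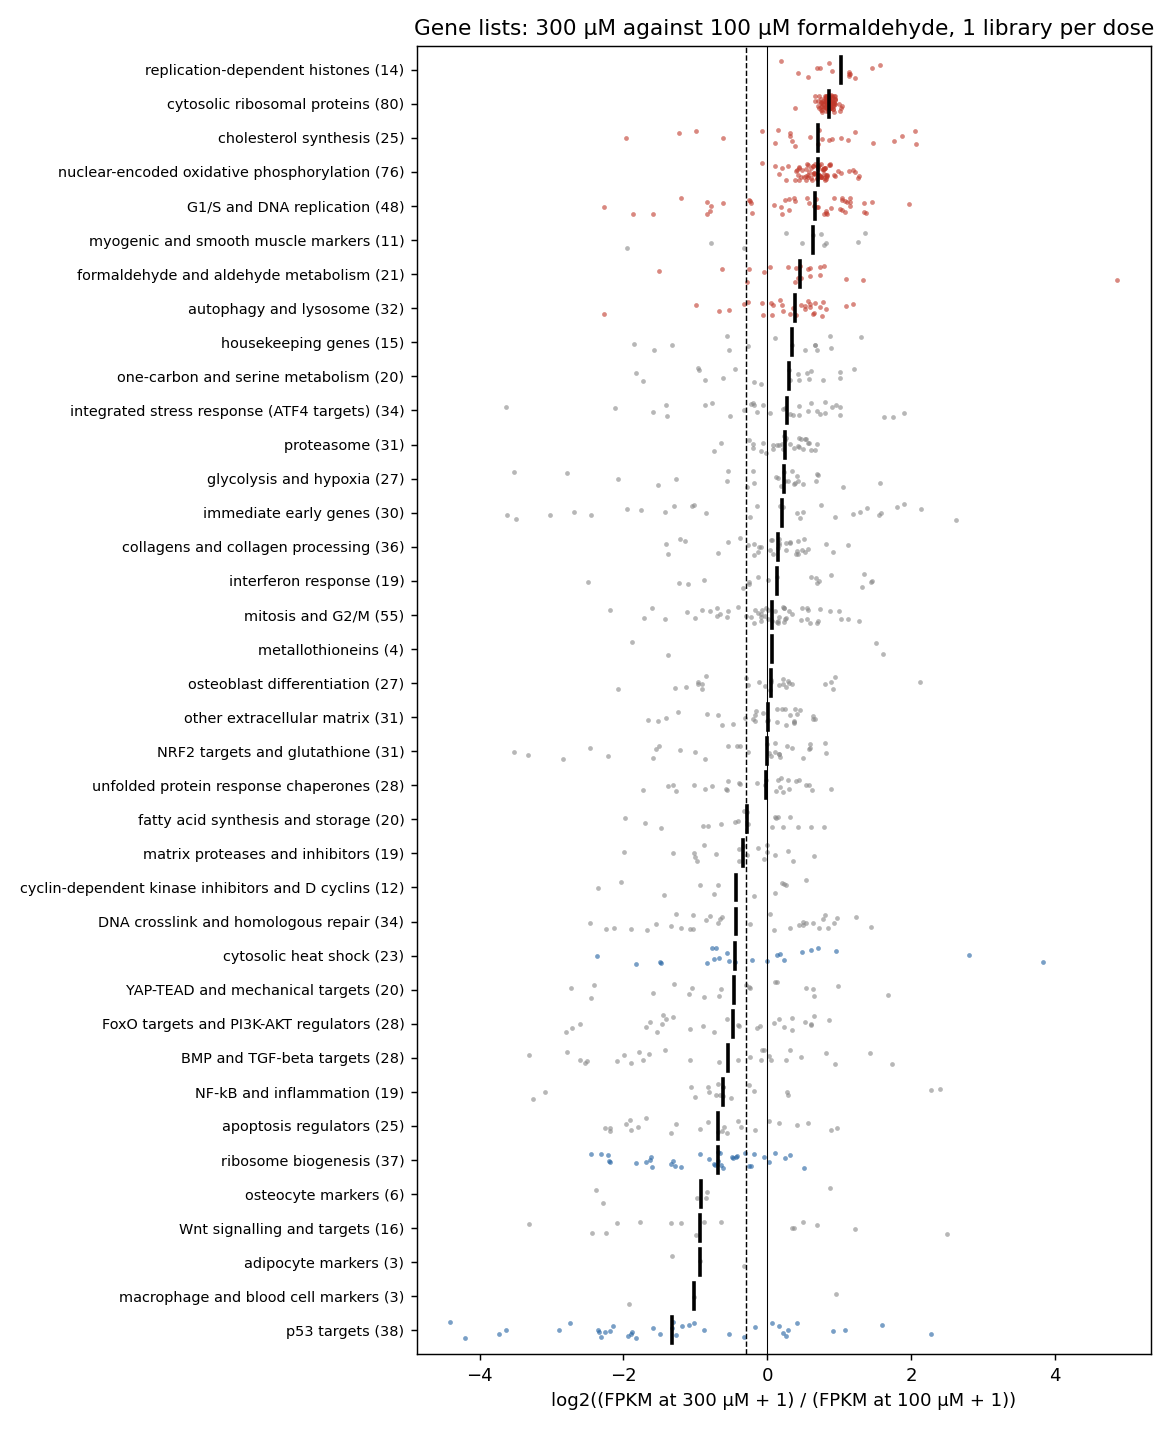
Each point is a gene, placed by its log2 ratio of FPKM + 1 at 300 µM over 100 µM (x axis), in rows by gene list with the number of genes compared; black bars are list medians, the dashed line is the median of all compared genes (-0.30), and red and blue mark the 7 lists in the top 2.5% and the 3 in the bottom 2.5% of level-matched random lists. The p53 targets lie lowest of the lists in colour (median -1.32), and the replication-dependent histones (1.02) and ribosomal proteins (0.85) highest.

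Genes of translation and respiration were higher at 300 µM, by less than 2-fold in most cases. The 80 cytosolic ribosomal protein genes had a median log2 ratio of 0.85, with 3 at least 2-fold higher and 0 lower, and 77 higher after centring. The 76 nuclear-encoded genes of oxidative phosphorylation had a median of 0.70, with 6 higher and 0 lower (38 and 0 after centring), led by Ndufs4 and Ndufs7 of complex I (1.28 and 1.26). For both lists 0 of 10000 random lists reached the median. Ribosome biogenesis genes differed from the ribosomal proteins in direction: 0 of 37 were at least 2-fold higher and 14 were lower, with a median of -0.69 that 2 of 10000 random lists matched or undercut. That call was lost with random lists not matched on level (percentile 7.09). Myc, a transcription factor that drives growth, stood at 82.2 and 14.2 FPKM, and Utp15 at 17.4 and 2.71 FPKM, whereas Nhp2 had a ratio of 0.51. The 31 proteasome genes had 0 beyond 2-fold in either direction (median 0.24, percentile 24.2).

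The sterol synthesis list stood apart as higher at 300 µM. Of 25 genes compared, 8 were at least 2-fold higher, 2 lower and 15 between (13 higher and 1 lower after centring), with a median of 0.71 that 0 random lists reached. Fdft1 (squalene synthase) stood at 6.44 and 30.4 FPKM and Mvd (mevalonate decarboxylase) at 5.70 and 26.9 FPKM. Sqle (squalene epoxidase) went the other way, at 20.4 and 8.09 FPKM. Fatty acid synthesis and storage genes did not stand apart (0 of 20 higher, 3 lower, median -0.27, which is 0.02 after centring, percentile 61.8). Fasn, fatty acid synthase, had a ratio of -1.99. Lysosome and autophagy genes had a median of 0.38 at percentile 97.7, with 2 of 32 higher (Atg7 and Ctsl) and 1 lower (Ulk1), and 6 and 1 after centring, a call lost with a pseudocount of 0.1, without the filter, and with a mean of at least 10 FPKM.

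The list of formaldehyde and aldehyde metabolism stood apart as higher at 300 µM, with most members within 2-fold. Adh5, the glutathione-dependent formaldehyde dehydrogenase, stood at 53.8 FPKM at 100 µM and 71.1 FPKM at 300 µM, and Aldh2, the mitochondrial aldehyde dehydrogenase, at 108 and 146 FPKM. Of the 21 genes compared, 3 were at least 2-fold higher (Adh1 among them, and Cyp2e1, whose reads were not located) and 1 was lower (Aldh1a3, -1.51), and 6 and 1 after centring. The median of 0.45 lay at percentile 99.0, and at 97.2 with a mean of at least 10 FPKM, where it no longer stood apart. Genes of one-carbon and serine metabolism had a median of 0.31 at percentile 96.0, with 3 of 20 higher, among them Mthfd1l and Phgdh, and 2 lower, Slc25a32 among them. Phgdh shares 63.1% of its words with other genes. Interstrand crosslink and homologous repair genes had 2 of 34 higher, Fancl and Fancc, and 12 lower, among them Sprtn, a protease that degrades DNA-protein crosslinks, at 17.8 and 2.42 FPKM, and Slx4 at 8.17 and 0.93 FPKM (median -0.44, percentile 75.3). After centring on the median gene 8 repair genes were higher and 7 lower.

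Stress response genes went in both directions. Of 31 genes of the NRF2 and glutathione list, 0 were at least 2-fold higher and 10 lower (2 and 8 after centring). Nfe2l2, which encodes NRF2, stood at 74.6 and 6.54 FPKM and Srxn1 (sulfiredoxin) at 208 and 17.2 FPKM, while Hmox1 (heme oxygenase) had -0.86 and Nqo1 -0.54. The list's median was 0.00 and its mean -0.59, and the median lay at percentile 9.17. The list stood apart as lower with the mean over members, which 0 of 10000 random lists undercut, and at a mean of at least 10 FPKM (percentile 0.43). Cytosolic heat shock genes stood apart as lower (median -0.45, 6 of 10000 random lists as low), with Hspb8 and the cochaperone gene Bag3 at -2.37 and -1.82, although Hspa1b and Hspa1a were the 2 that were at least 2-fold higher, against 4 lower (4 and 4 after centring). That call was lost with the mean in place of the median (percentile 17.1) and with random lists not matched on level (percentile 32.7). Among 34 ATF4 targets of the integrated stress response, 5 were higher and 5 lower (10 and 5 after centring). Ddit3 (CHOP) stood at 16.5 and 52.8 FPKM, Atf3 at 3.19 and 14.7 FPKM and Ppp1r15a at 22.4 and 77.6 FPKM, whereas Sesn2 and Cebpg had -3.64 and -2.12 and Atf4 itself 0.80 (median 0.28, percentile 86.6). Unfolded protein response chaperones had 0 of 28 higher and 5 lower, and 1 and 3 after centring (median -0.02, percentile 27.2), with Syvn1 lowest at -1.73. The metallothionein genes Mt2 and Mt1 had ratios of 1.61 and 1.51, and their regulator Mtf1 -1.88, so that of the 4 genes of that list 2 were higher and 2 lower (median 0.06, percentile 74.2). Of 25 apoptosis regulators, 0 were higher and 10 lower, Fas and the TRAIL receptor gene Tnfrsf10b among them (-2.26 and -2.19, list median -0.68, percentile 9.16, and 2.38 with the mean over members).

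Immediate early genes split within the list. Of 30, 9 were at least 2-fold higher, led by Fos (7.35 and 50.4 FPKM) and Zfp36 (16.0 and 73.7 FPKM), and 11 were lower, led by Dusp4 (19.8 and 0.69 FPKM) and Fosl2 (32.1 and 1.93 FPKM). The balance turned after centring, with 11 higher and 8 lower. Their median of 0.20 lay at percentile 84.7 and their mean was -0.20. Of 19 inflammatory genes, 2 were higher, the chemokine genes Ccl7 and Ccl2 (2.40 and 2.28), and 4 lower, with Il1rl1 at 176 and 17.5 FPKM and Il11 at 52.0 and 5.22 FPKM (median -0.62, percentile 14.7, and 2 higher and 2 lower after centring). Interferon response genes had 4 of 19 higher and 3 lower, and 6 and 1 after centring, with Xaf1 at 1.46 and Trim25 at -2.50. Their median was 0.14, at percentile 97.46, just inside the bound, and at 99.79 with the mean over members. The percentile was 92.3 without the filter, 91.35 with unmatched random lists and 86.2 with lists matched on transcript length as well as level.

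Osteoblast genes differed little as a group. Of 27 compared, 1 was at least 2-fold higher, Omd (osteomodulin, 1.52 and 9.94 FPKM), and 3 were lower, Dlx5 (32.9 and 7.04 FPKM) and Tnfrsf11b (osteoprotegerin, 22.9 and 8.80 FPKM) among them. After centring 5 were higher and 1 lower. The list median was 0.05 at percentile 80.3. Runx2, the master transcription factor of the lineage, stood at 7.99 and 3.60 FPKM, a ratio of 2.22 that lies within 2-fold once the pseudocount of 1 is added (log2 ratio -0.97), and Sp7 (osterix) at 7.21 and 9.47 FPKM. Col1a1 stood at 2065 and 1714 FPKM (-0.27, a sign that flips after centring) and Spp1 (osteopontin) at 253 and 313 FPKM. Alpl (alkaline phosphatase) was near 1 FPKM in both, at 0.98 and 1.06, and Bglap (osteocalcin, 74.7% of its words shared with other genes) was listed at 0 at 100 µM and 0.49 FPKM at 300 µM. Collagen genes had 1 of 36 higher and 4 lower (3 and 2 after centring). The gene higher was Loxl2, which shares 45.8% of its words with other genes, and among those lower were the crosslinking enzyme genes Lox and Plod2 (-1.41 and -1.38; list median 0.15, percentile 64.1). Other matrix genes had 0 of 31 higher and 4 lower (median 0.02, percentile 27.5), with Emilin1 at -1.66. Matrix proteases and their inhibitors had 0 of 19 higher and 4 lower, among them Adamts1, at 18.6 and 6.91 FPKM, and 0 and 2 after centring (median -0.34, percentile 10.1).

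**Figure D2:**
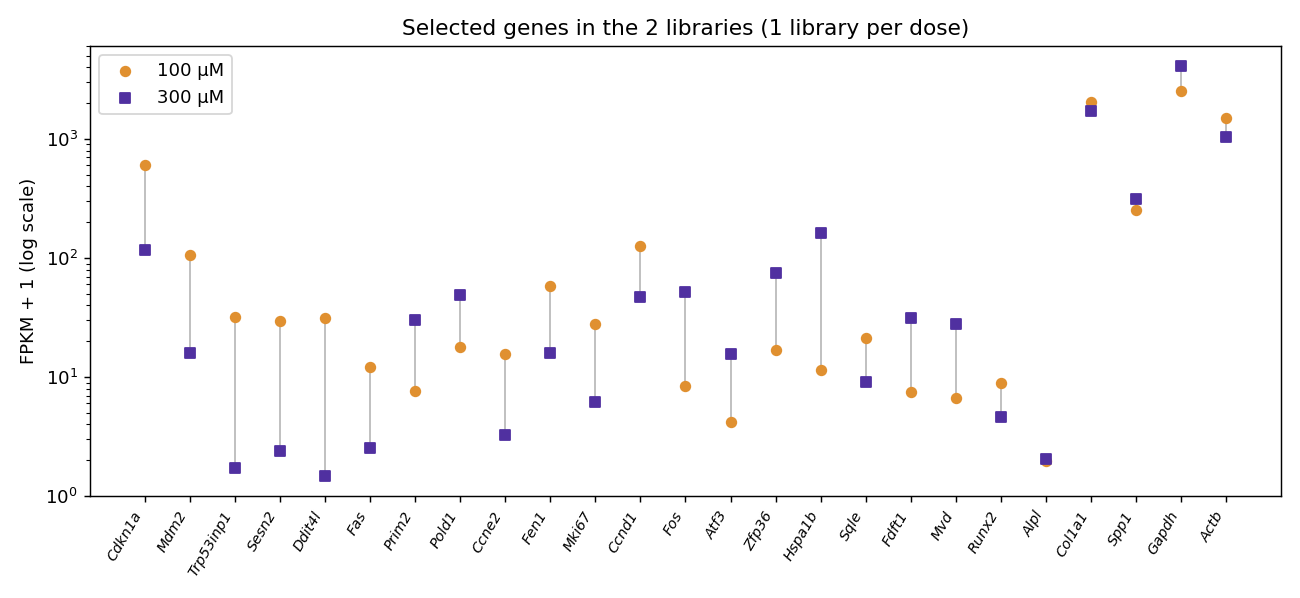
FPKM + 1 on a log axis (y) of 25 named genes (x) in the library of 100 µM (circles) and of 300 µM (squares), 1 value per dose and no error bars because there are no replicates. Cdkn1a, Mdm2, Trp53inp1, Sesn2, Ddit4l and Fas lie lower at 300 µM, Prim2, Pold1, Fos, Atf3, Zfp36, Hspa1b, Fdft1 and Mvd lie higher, and Col1a1 (2065 and 1714 FPKM) and Spp1 (253 and 313 FPKM) lie close together.

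Signalling lists had more genes lower than higher, as did all genes compared (29.8% lower and 6.09% higher). Their medians lay within the central 95% of random lists in the main setting. Of 16 Wnt genes 7 were lower and 2 higher, and 6 and 2 after centring (median -0.93, percentile 3.27). The Wnt list stood apart as lower with pseudocounts of 0.1 and 5 (percentiles 1.75 and 2.11), but at a mean of at least 10 FPKM its median over 7 genes was 0.35. It held the Wnt-induced genes Ccn4 at 33.9 and 2.49 FPKM and Ccn5 at 44.1 and 254 FPKM. Of 28 BMP and TGF-beta genes 13 were lower, Inhba furthest (-3.31), and 2 higher, the BMP targets Id3 and Id1 (1.73 and 1.43). After centring 12 of them were lower and 4 higher. The median of the BMP and TGF-beta list was -0.54, at percentile 6.5. That list stood apart as lower with a pseudocount of 0.1 (percentile 2.12) and with the mean over members (0.4). It lay well within the bounds with a pseudocount of 5 (20.5), without the filter (21.6) and at a mean of at least 10 FPKM (26.1). With random lists matched on transcript length as well as level it lay at percentile 21.2. FoxO and PI3K-AKT genes had 11 of 28 lower, Irs2 and Bcl6 furthest (-2.80 and -2.72), and 0 higher, and 10 and 1 after centring (median -0.48, percentile 36.4, and 0.10 over 11 genes at a mean of at least 10 FPKM). YAP-TEAD targets had 7 of 20 lower and 1 higher, and 4 and 2 after centring (median -0.47, percentile 15.6), with Amotl2 at -2.74 and Gadd45b at 1.67. Glycolysis and hypoxia genes had 5 of 27 lower and 2 higher, and 4 and 3 after centring (median 0.23, percentile 85.0), with the growth factor gene Vegfa at 91.8 and 7.08 FPKM and Hk2 (hexokinase) at 15.1 and 1.33 FPKM.

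Markers of other cell types were mostly below the level compared. At a mean of at least 1 FPKM there were 3 adipocyte genes (median -0.94), 3 macrophage and blood cell genes (-1.01) and 6 osteocyte genes (-0.92, percentile 4.6), none of these lists beyond the bounds in the main setting. The blood cell genes went both ways: Lyz2 (lysozyme) stood at 13.2 and 26.5 FPKM (0.95), while Cd14 and Cd68 had -1.92 and -1.01. The osteocyte list stood apart as lower with a pseudocount of 5, with the mean over members and at a mean of at least 10 FPKM (percentiles 2.21, 1.48 and 0.13). There were 2 chondrocyte genes, Col2a1 at 322 and 350 FPKM and Sox9 at 61.4 and 9.78 FPKM. The 11 myogenic and smooth muscle genes had a median of 0.64 at percentile 96.2, with Acta1 at 1.37 and Myl9 at 1.26. The endothelial, neuronal and epithelial lists had 1 gene each, Flt1 (0.03), Tubb3 (-0.98) and Krt14 (-0.24, a sign that flips after centring). Housekeeping genes were not level: 1 of 15 was at least 2-fold higher and 3 were lower, Tfrc (-1.85) and Tbp (-1.58) among them, with 3 and 3 after centring. Gapdh, which shares 82.5% of its words with pseudogenes or other genes, had 0.69 and Actb -0.53 (list median 0.35, percentile 53.2). Of the 15 mitochondrially encoded transcripts on the list, 0 were found in the tables.

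The ratio varied with the length of the transcript. In the decile of shortest transcripts (293 to 1222 bases) the median log2 ratio was 0.61, and it decreased in every decile to -1.06 among the longest (6247 bases and more). Spearman's rho with transcript length was -0.41 across 10093 genes, which are not independent replicates. By gene span the course was different: the median decreased to -0.59 in the ninth decile and was 0.16 in the decile of longest spans, those above 102795 bases. When random lists were matched on transcript length as well as level, an alternative chosen after seeing the data, the 10 lists that stood apart kept their calls. Collagen genes, one-carbon metabolism, ATF4 targets, and glycolysis and hypoxia genes then stood apart as higher too, at percentiles 99.8, 99.1, 98.7 and 97.7. This matching used 5 bins of level and 5 of length, against 20 bins of level in the main setting. Its shortest bin joined the deciles with medians of 0.61 and 0.25. The median transcripts of the ribosomal protein, oxidative phosphorylation and histone lists (869, 870 and 667 bases) lie in the shorter of these. For these lists length was therefore matched only coarsely.

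**Figure D3:**
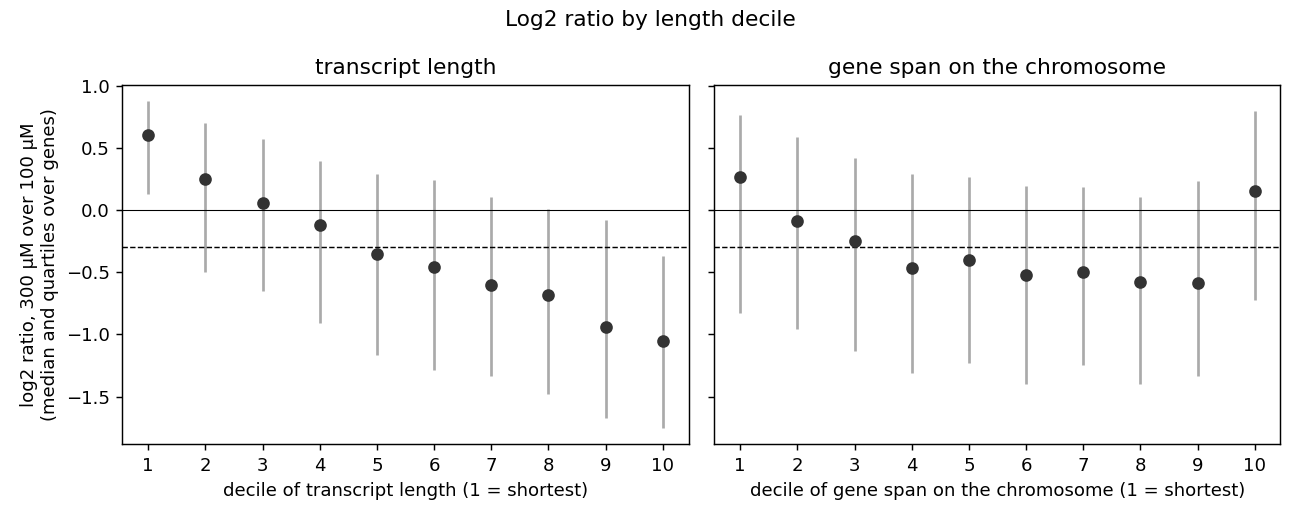
Median log2 ratio of FPKM + 1 at 300 µM over 100 µM (y axis; bars are quartiles over genes, not errors between replicates) in deciles of transcript length (left) and of gene span on the chromosome (right), with the median of all compared genes dashed. The median runs from 0.61 to -1.06 with transcript length, and by span it is 0.16 in the longest decile against -0.59 in the one before.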

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

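The trend removal on transcript length and GC content and the random lists matched on transcript length were chosen after seeing the data, and the other alternatives before. The count of genes at least 2-fold higher (616) became 1472 with centring on the median gene, 1829 with the TMM factor (a shift of -0.40 in log2) and 1125 with the length and GC trend removed, which also removes the median shift. It was 258 with a pseudocount of 5, 358 with a mean of at least 10 FPKM (5340 genes compared), 1901 at 1.5-fold and 123 at 3-fold. The count at least 2-fold lower (3020) became 1630 with a pseudocount of 5, 1141 with a mean of at least 10 FPKM, 1653 at 3-fold and 1797 with the trend removed. It stayed within 1.5 times with centring (2261) and TMM (2045), and lower genes outnumbered higher ones under every alternative run. Lists in the top 2.5% of random lists (7) became 14 with unmatched random lists and 11 with length matching. Lists in the bottom 2.5% (3) became 5 with either pseudocount, 6 with a mean of at least 10 FPKM, 6 with the mean over members and 1 with unmatched random lists, which left the p53 targets. Replication genes, histones, p53 targets, sterol synthesis, oxidative phosphorylation and ribosomal proteins kept their calls under every alternative that gave them a value, and no list called in the main setting changed sign. Of lists not called there, one-carbon metabolism stood apart as higher with a pseudocount of 5 and the myogenic list with 0.1 (percentiles 97.8 and 98.35). With unmatched random lists these and the ATF4 targets, immediate early genes, collagens, glycolysis and proteasome did so, and interferon genes did at a mean of at least 10 FPKM (5 genes, percentile 99.39). In 9 lists the median was positive and the mean negative, or the reverse. Of 186 named genes, 134 lay beyond 2-fold, and 143, 113 and 148 with pseudocounts of 0.1 and 5 and with TMM. Counting error is small at about 18500000 fragments, but 1 library per dose leaves the variation between cultures unknown. No paired analysis was possible because each dose has 1 library. The planned counting-interval alternative was not run, since the values are not counts, and the planned comparison with untreated cells was not run, since the tables hold none.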

Other observations

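The tests below on the exposure dose, unspecific reads, depth and exchanged labels, and the gene groups of this first paragraph, were chosen after the values they rest on were seen. Zinc finger genes were lower at 300 µM as a class. Of 267 genes with a Zfp symbol, 198 were at least 2-fold lower and 4 higher, with a median log2 ratio of -1.45, and 0 of 10000 random lists matched on level and transcript length had a median as low. Dual specificity phosphatase genes, taken by their Dusp symbol and only some of which restrain MAP kinases, had 8 of 14 lower and 1 higher (median -1.58, as low in 4 of 10000 such lists). Ubiquitin-specific protease genes had 20 of 39 lower and 0 higher (median -1.04), which lay at percentile 15.1 of lists matched on level and transcript length and 1.30 of lists matched on level alone. Solute carriers had 65 of 161 lower and 6 higher (median -0.74, percentile 1.02). Mitochondrial ribosomal protein genes had a median of 0.28, with 4 of 78 higher and 5 lower. That median lay at percentile 33.2 of lists matched on level and transcript length, but at 98.39 of lists matched on level alone. Rab GTPase, kinesin and Nduf genes were run too, at percentiles 45.9, 94.8 and 98.97 of lists matched on both.

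Genes that span 100 kb or more were higher at 300 µM than shorter genes. This class was not among the comparisons planned before the data were examined, and the shuffled intervals below do not allow for its choice. Their median log2 ratio was 0.13 over 1069 genes against -0.35 over 9024 shorter genes, and 17.0% of them against 4.80% were at least 2-fold higher. The median was -0.13 for spans of 100 to 200 kb, 0.67 from 200 to 400 kb and 0.72 above. Matched on transcript length, GC content and level, the difference widened to 0.95 (central 95% of shuffled labels -0.10 to 0.09), which argues against these 3 properties as its cause. Among genes with 1 transcript in GENCODE release M21 the difference was 1.07 (shuffled -0.53 to 0.57), though only 21 long genes entered. The annotation used with RSEM is not known and may hold more isoforms of these genes. This value therefore does not decide whether reads moved to short isoforms. An even floor of unspecific reads, such as genomic DNA, is argued against by the lower quartile of all 2265 listed genes of that span. It was 0.02 FPKM at 300 µM (95% bootstrap bounds 0.01 to 0.02). Such a floor would have to add 2.40 FPKM to the median long gene compared (quartiles 1.35 to 5.52) to give the matched difference. Unspecific reads that are not even across genes were not tested, because that quartile bears only on an even floor. The dose may be the cause, which stays open with 1 library per dose. The division of reads among isoforms and uneven unspecific reads stay open too.

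Genes with long transcripts were lower at 300 µM, with medians from 0.61 in the shortest decile to -1.06 in the longest. A bias against long transcripts as such was set against collagen and other matrix genes, whose median transcript of 4438 bases exceeds the 2966 bases of all genes compared. Their median ratio was 0.13, where 67 genes matched on transcript length and level gave -0.32 (percentile 99.97). The collagen list alone lay at percentile 99.83 and the other matrix list at 90.14, within the central 95%, so length alone does not account for the collagen genes, and for the other matrix genes this is not shown. Genes with an AU-rich nonamer in the 3' UTR, a mark of unstable mRNA, had a median of -0.73 against -0.22 without, but matched on 3' UTR length, transcript length and level the difference was -0.067 (shuffled -0.088 to 0.058), and the depths differed by 1.05 times. What remains open is a partial length effect of library preparation beside a difference in mRNA turnover, which these values could both produce.

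The p53 targets were lower at 300 µM than at 100 µM and the replication genes higher. Transcript length and level are argued against as a cause by percentile 0 of the p53 target median among lists matched on both. The AU-rich nonamer in the 3' UTR is argued against likewise, with percentile 0 among lists matched on the nonamer, 3' UTR length and level, where 0 of 10000 lists were as low, and 10 of the 38 targets carry the nonamer. The nonamer itself made no matched difference beyond shuffled ones (-0.067, shuffled -0.088 to 0.058). Matching on it therefore does not control for mRNA turnover, which stays open for the p53 targets too. An exchange of the labels of the 2 libraries cannot be told apart from an effect of the dose, because 0 untreated libraries were among the samples used, and the dose itself stays untested with 1 library each.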
